A study of Mus musculus with 7 samples.

How the data were processed

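RNA from the retinal pigment epithelium of 7 mouse samples was profiled on Affymetrix whole-transcript gene arrays, 4 samples from wild-type C57BL/6J mice and 3 from Mfrp rd6 mutants. Per the labels' protocols, the cornea and lens were taken off, the eyecups were agitated in an RNA-preserving solution until the RPE came loose, and the cells were spun down. Per the labels' protocols, RNA was purified on Qiagen columns, and cDNA was made with the Ambion WT kit and labelled with biotin by terminal labelling. This collection takes along whatever else comes loose from the eyecup, so marker lists for other cell types were included.

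The authors deposited 1 table of log2 values, with 1 value per probe set and array. Per the submitters' processing notes, these log2 values were made by the authors with Affymetrix Expression Console and RMA, a method that corrects the background, makes the probe distributions of the arrays equal and summarises the probes of a set; versions and library files are not given in the sources used here. RMA compresses changes of dim probe sets, so log2 changes near the floor are understated. The probe values lay between 1.91 and 13.81. Scanner values, slides and scan dates were not used here.

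Probe sets were named from the platform annotation, which can be old. Of 35556 probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 had none. An Entrez identifier in the RefSeq gene table of assembly GRCm38.p6 was matched for 21698 of the 1-symbol probe sets, and 0 symbols needed an update. No gene was named from a probe set with several symbols, with the exception that the probe set annotated to both Mfrp and C1qtnf5 was reported as such. For the 999 genes with more than 1 probe set, the one with the highest mean over all arrays was used, which left 19938 genes. Among changed genes, 15 had more than 1 probe set, and in 2 of these another probe set had the opposite sign.

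Samples were grouped by the genotype in the labels. Each gene was fitted with limma (version 3.58.1, lmFit and eBayes, R 4.3.3) as Mfrp rd6 minus wild type, with 5 residual degrees of freedom and a prior of 4.56, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. No filter on dim probe sets and no block was used. The design, the alternatives, 34 gene lists with 573 entries and the rule for named genes were set before the data were examined. Of the entries, 521 were measured, 12 lay only on a probe set shared with another gene, 39 had no match and 1 repeated a member. Each list's counts are given over all genes and adjusted over the list alone. The 32 lists with at least 5 measured genes were tested with limma's camera (preset correlation 0.01, and an estimated correlation as an alternative) and with fry, adjusted over the lists. List means were also compared by an exact two-sided permutation test over the 35 splits of the 7 arrays into 3 and 4. Named were Mfrp, C1qtnf5, Adipor1, Prss56 and Rpe65 (a further gene of this part of the rule is not reported here), the 10 genes with the largest rise and the 10 with the largest fall among changed genes with complete separation of the arrays (leaving out predicted, clone, small RNA, olfactory and vomeronasal names), and from each list the 2 members past the threshold with the largest change or, with none, the brightest member. Other genes named in the text were chosen after their values were seen.

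The procedure was tested on simulated data for the same 19938 genes and 7 arrays. At a true log2 change of 0.5, 80% of 50 changed genes were recovered, and 98% at 1. Of 201 calls, 12 were false (5.97%). For a simulated list shifted by 0.3, camera gave an adjusted p of 1.39e-20, and 1 of the 31 other lists was called. The simulated genes varied independently of each other, while in the data the estimated correlation reached 0.884 for the skeletal muscle list. The simulation therefore does not show how often camera calls unchanged lists in these data.

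Alternatives were other normalizations between arrays, filters on dim genes, a variance trend with robust moderation, array weights, the mean of a gene's probe sets, the replicate number as a block, marker means of rods or of microglia and macrophages as covariates, a minimum change of 1 log2 unit, all probe sets, and leaving out each array. Leaving out wild-type replicate 3 with Mfrp rd6 replicate 2, and a skeletal muscle marker mean as a covariate, were added after seeing the data. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and figures.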

Results

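Expression was measured in the retinal pigment epithelium (RPE), the pigmented cell layer that nourishes the photoreceptors and recycles visual pigment, of C57BL/6J mice. Each of 7 RNA samples was hybridised to 1 whole-transcript array, 4 from wild type and 3 from Mfrp rd6 mutants, and the comparison asked how the mutant RPE differs from the wild-type RPE. Mfrp encodes a membrane protein with a frizzled-like domain that the RPE makes, and the recessive rd6 allele leads to retinal degeneration. On the log2 scale the array medians lay between 6.52 and 6.58, the lower quartiles between 4.90 and 5.02 and the upper quartiles between 8.41 and 8.51. Correlations across probe sets were 0.994 to 0.997 within wild type (6 pairs), 0.995 to 0.996 within Mfrp rd6 (3 pairs) and 0.990 to 0.994 between the groups (12 pairs). The first principal component, with 43.1% of the variance, separated the groups. The number of arrays limits the precision, and the median standard error of a gene's log2 change was 0.09. The labels give 2 versions of the ages. The age field puts all 3 Mfrp rd6 samples at 12 weeks and all wild-type samples at 8 weeks, so that age and genotype cannot be told apart, while the growth protocol puts only Mfrp rd6 replicate 1 at 12 weeks. Nothing in the labels says that the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

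The mutated gene was represented by 1 probe set (10584653) that is annotated to both Mfrp and its neighbour C1qtnf5, so the transcripts could not be told apart. Its signal was high in both groups, at 11.33 ± 0.12 (SD, n = 4) in wild type and 11.17 ± 0.07 (SD, n = 3) in Mfrp rd6. The change of -0.16 (95% confidence interval -0.35 to 0.03) did not pass the test (limma, adjusted p = 0.409). An exact two-sided permutation test over the 35 splits of the arrays gave p = 0.143, where 0.0286 is the smallest value possible. The rd6 allele is known as a deletion at a splice donor, so a probe set of this kind does not check the genotype labels. Of the 6 measured genes tied to eye size and to Mfrp, 0 rose and 0 fell, as also when adjusted over the list alone, and the list was not called (limma's camera, adjusted p = 0.485). Adipor1, an adiponectin receptor with a similar mutant retina, read 11.34 ± 0.06 in wild type and 11.33 ± 0.02 in Mfrp rd6. Prss56, a serine protease linked to small eyes, read 6.31 ± 0.11 and 6.32 ± 0.18, and Tmem98, a membrane protein of the RPE, differed by -0.01.

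The largest rises in the Mfrp rd6 samples were those of Ly86, Cst7, Tyrobp and C4b, and the largest falls those of Serpine3, Htr3a and Upk3b. Of 19938 genes tested, 429 changed at a limma adjusted p under 0.05, 267 higher and 162 lower in Mfrp rd6. By at least 1 log2 unit, 88 genes rose and 16 fell. Ly86, a myeloid partner of a toll-like receptor homologue, rose 10.7-fold from 6.63 ± 0.15 (SD, n = 4) to 10.04 ± 0.36 (SD, n = 3), a log2 change of 3.41 (SE 0.15, adjusted p = 4.9e-06). Cst7, a cysteine protease inhibitor of immune cells, rose by 3.24 (SE 0.14, adjusted p = 4.9e-06), and the signalling adaptors Tyrobp and Fcer1g rose by 3.18 and 2.96. C4b, the complement component cleaved by the C1 complex, rose from 7.30 ± 0.16 to 10.45 ± 0.13 (adjusted p = 1.21e-06), the smallest p of all genes. The 3 chains of C1q rose by 2.90 (C1qa), 3.09 (C1qb) and 3.11 (C1qc). The complement protease Cfi rose by 2.96 and the lipid receptor Trem2 by 2.72. With the skeletal muscle mean as a covariate C1qa (2.63, adjusted p = 0.0558) and Trem2 (2.16, adjusted p = 0.147) did not pass. With the microglia and macrophage mean as a covariate, which nearly coincides with genotype, 0 of the 19938 genes passed. In that fit the change was 0.05 for C1qa and -0.33 for Trem2, both members of the covariate's list. Over all alternatives, that fit included, the lowest rise was 3.07 for C4b and 2.79 for Cfi. It was 1.54 for Cst7, 1.38 for C1qb, 1.30 for Ly86, 1.08 for C1qc, 0.98 for Tyrobp and 0.75 for Fcer1g.

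The 10 largest falls began with Serpine3, a member of the serpin family, at -2.93 (SE 0.43, adjusted p = 0.00983), which reached 6.07 ± 0.16 (SD, n = 3) in Mfrp rd6 and spread widely in wild type (SD 0.99, n = 4). Serpine3 did not pass with a variance trend and robust moderation (adjusted p = 0.0601), with the rod mean (adjusted p = 0.0591), skeletal muscle mean (adjusted p = 0.335) or microglia and macrophage mean (adjusted p = 0.999) as a covariate, or without wild-type replicate 3 and Mfrp rd6 replicate 2 together (adjusted p = 0.0728). Its change stayed between -3.79 and -2.54 in all 20 alternatives. Htr3a, a subunit of the serotonin-gated channel, fell 6.95-fold (-2.80, SE 0.20) from a wild-type level of 9.80 ± 0.39 (adjusted p = 9.52e-05). Upk3b, a uroplakin, fell from 9.55 ± 0.44 to 6.85 ± 0.14 (adjusted p = 0.000125), and Stox1, a winged-helix DNA-binding protein, fell by 2.36 on the log2 scale. Wfikkn2, a secreted antagonist of growth factors of the myostatin type, fell from 10.94 ± 0.16 to 8.69 ± 0.20 (adjusted p = 1e-05). Map6d1 (-1.88), the adrenomedullin receptor partner Ramp2 (-1.60), the actin-bundling protein Fscn1 (-1.53), the BMP antagonist Nog (-1.40) and the lipid carrier Mfsd2a (-1.15) fell as well. Nog did not pass without wild-type replicate 3 and Mfrp rd6 replicate 2 together (adjusted p = 0.0566) or with the skeletal muscle mean as a covariate (adjusted p = 0.256). The change of Nog stayed between -1.51 and -0.99 in all 20 alternatives. In all 429 changed genes every Mfrp rd6 array lay beyond every wild-type array, as in 3058 genes tested (15.3%, where chance gives 5.71%). Leaving out 1 array gave 211 changed genes without Mfrp rd6 replicate 1, 243 without Mfrp rd6 replicate 2, and 266, 269 and 279 without wild-type replicates 2, 4 and 1. Without Mfrp rd6 replicate 1, the fit that compares equal ages under the growth protocol, 152 genes rose and 59 fell, and 201 of the 429 were among them.

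**Figure D1:**
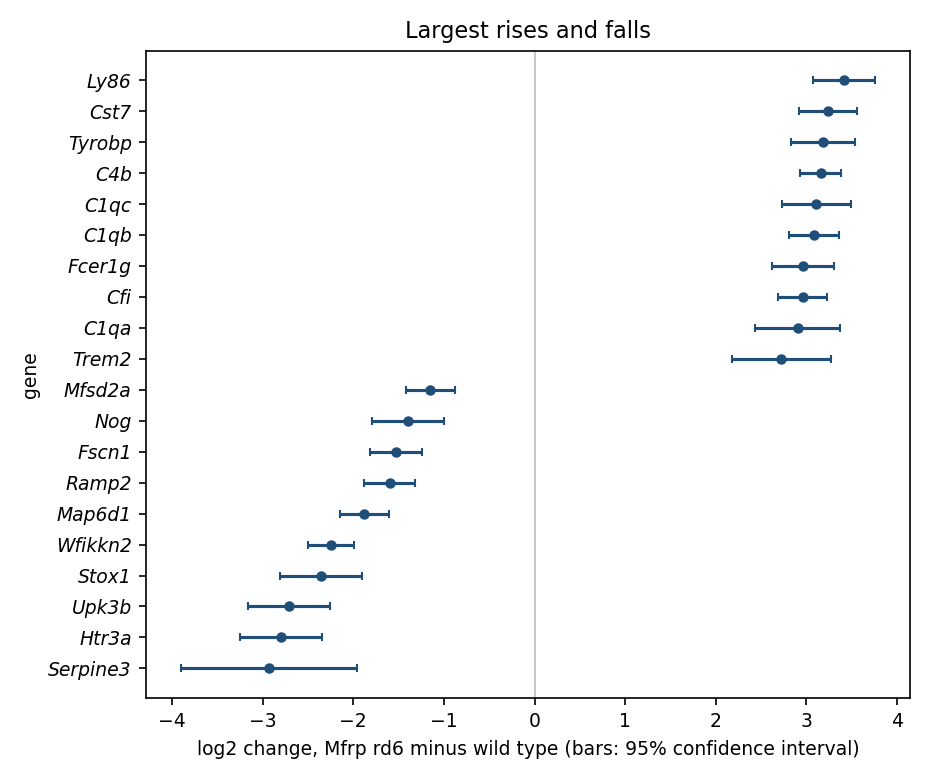
Log2 change (Mfrp rd6 minus wild type, horizontal axis) of the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, 1 gene per line, with 95% confidence intervals as bars. The rises reach 3.41 for Ly86, the falls reach -2.93 for Serpine3, and the interval of Serpine3 is the widest.

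Markers of microglia and macrophages rose together. Of 21 measured members, 17 rose and 0 fell in Mfrp rd6 (19 and 0 adjusted over the list alone). Their mean was 7.12 ± 0.04 (SD, n = 4) in wild type and 8.93 ± 0.31 (SD, n = 3) in Mfrp rd6, a difference of 1.81. Tyrobp (3.18) and C1qc (3.11) had the largest rises in the list. Beside them, chosen after their values were seen, were Mpeg1, a pore-forming protein of macrophages (2.45), the microglial receptor Cx3cr1 (1.34) and the microglial surface proteins Tmem119 (1.27) and P2ry12 (1.20). The 4 members that did not pass were Ptprc (0.52), Csf1r (0.40), Itgam (-0.12) and Mrc1 (-0.17). The list was called higher by limma's camera with a preset correlation (adjusted p = 1.91e-41), with adjusted p = 0.217 with an estimated correlation, and limma's fry, which asks only whether the members move one way, gave an adjusted p of 0.00188. An exact permutation test of the list means gave p = 0.0286, the smallest possible, or 0.162 after adjustment over the 34 lists. The skeletal muscle markers were also higher in these arrays, by a mean of 1.37.

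Complement genes rose in part. Of 15 measured members, 4 rose and 0 fell (7 and 0 adjusted over the list alone), namely C4b (3.16), Cfi (2.96), the anaphylatoxin receptor C3ar1 (2.04) and the C1 protease C1ra (0.77), the last 2 named after their values were seen. The list mean rose by 0.65 and the median member by 0.22 (camera adjusted p = 7.69e-07, adjusted p = 0.227 with an estimated correlation, fry adjusted p = 0.00279). C4b has a near-identical paralogue, C4a, which was higher too (adjusted p = 0.0109), so the split between them is uncertain. The complement regulators Cd55 (-0.19) and Cd46 (-0.06) did not pass. The microglia and macrophage mean was higher in the same arrays by 1.81, and with it as a covariate the complement list was not called (0.56, adjusted p = 0.0514). That mean nearly coincides with genotype, so little of the contrast is left to estimate. Over all alternatives, that fit included, C4b rose by at least 3.07 and Cfi by at least 2.79, though neither passed in that fit.

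The lists for antigen presentation and the interferon response held no changed gene. In the antigen presentation list, 0 of 13 members changed, also adjusted over the list alone, with B2m, the light chain of class I molecules, 0.15 higher (adjusted p = 0.29). The mean difference of 0.13 was called higher by camera (adjusted p = 0.0276, adjusted p = 0.568 with an estimated correlation). On the same arrays the microglia and macrophage mean was higher by 1.81 and the skeletal muscle mean by 1.37. The call was lost without wild-type replicate 1 (antigen presentation 0.08, adjusted p = 0.0674) and without Mfrp rd6 replicate 3 (0.09, adjusted p = 0.219), and also with array weights (adjusted p = 0.115) or the rod mean as a covariate (adjusted p = 0.104). Of 16 interferon response genes 0 changed, also adjusted over the list alone, and the list was not called (mean difference 0.10, adjusted p = 0.0872). Its brightest member, Oasl2, differed by -0.09. Without wild-type replicate 4 (interferon response 0.17, adjusted p = 0.00125) or Mfrp rd6 replicate 1 (0.16, adjusted p = 0.0341) the list was called higher, as with the skeletal muscle mean as a covariate (0.22, adjusted p = 0.00336), and in all it was called in 4 of 20 alternatives. Without Mfrp rd6 replicate 3 the interferon response difference was 0.04 (camera adjusted p = 0.514).

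The mean of lysosomal genes was slightly higher in Mfrp rd6. Of 23 measured members 2 rose and 0 fell (7 and 0 adjusted over the list alone), the protease Ctsz by 0.56 (adjusted p = 0.0154) and the glycoprotein Gpnmb by 0.40, from 11.83 ± 0.06 to 12.23 ± 0.03 (adjusted p = 0.015). The lysosome list mean was 0.14 higher (camera adjusted p = 8.43e-06, adjusted p = 0.568 with an estimated correlation). The microglia and macrophage mean was higher on the same arrays by 1.81 and the skeletal muscle mean by 1.37. With the first as a covariate, which nearly coincides with genotype, the lysosome difference was -0.21 and that of Ctsz -0.27, and with the second the lysosome difference was 0.00 (adjusted p = 0.455). Ctsz did not pass without Mfrp rd6 replicate 1 (0.57, adjusted p = 0.058) or 2 (0.49, adjusted p = 0.0658), and Gpnmb did not pass without Mfrp rd6 replicate 1 (0.39, adjusted p = 0.0681) or 2 (0.40, adjusted p = 0.061) or wild-type replicate 4 (0.39, adjusted p = 0.0561). Over all alternatives Ctsz passed in 13 of 20 and Gpnmb in 12 of 20.

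The mean of genes of the RPE visual cycle, which rebuilds the chromophore of the visual pigments, was slightly lower in Mfrp rd6. Of 10 measured members 0 rose and 2 fell, also adjusted over the list alone. Rdh10, a retinol dehydrogenase, fell from 12.62 ± 0.09 (SD, n = 4) to 12.09 ± 0.15 (SD, n = 3), a change of -0.54 (adjusted p = 0.0143). Lrat, which esterifies retinol, fell from 12.86 ± 0.07 to 12.46 ± 0.09 (-0.40, adjusted p = 0.0277). Rpe65, the isomerase of the cycle, read 12.87 ± 0.05 and 12.64 ± 0.16 (-0.22, adjusted p = 0.24). The list mean differed by -0.16 (camera adjusted p = 0.0218, adjusted p = 0.568 with an estimated correlation), and the call on the RPE visual cycle was lost without Mfrp rd6 replicate 3 (-0.11, adjusted p = 0.216), with array weights (-0.13, adjusted p = 0.0678), and when only genes above the median level (adjusted p = 0.119) or with a mean of at least 6 (adjusted p = 0.0667) were tested. On the same arrays the microglia and macrophage mean was higher by 1.81, the skeletal muscle mean by 1.37 and the choroidal endothelial mean by 0.40. The RPE visual cycle difference was -0.60 with the first as a covariate and -0.29 with the second. Rdh10 passed in 15 of 20 alternatives. It did not pass with the replicate number as a block, without Mfrp rd6 replicate 1 (-0.53, adjusted p = 0.0598) or with the rod mean (-0.46, adjusted p = 0.125), skeletal muscle mean (-0.76, adjusted p = 0.124) or microglia and macrophage mean (-1.40, adjusted p = 0.915) as a covariate. Lrat passed in 9 of 20 alternatives, and of the 7 fits that each left out 1 array Lrat passed only in that without wild-type replicate 1, with changes of -0.44 to -0.35 and adjusted p up to 0.0908.

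In the lists for RPE identity few genes changed. Among 16 genes of melanin synthesis and melanosomes, 1 rose and 0 fell (1 and 1 adjusted over the list alone): Gpr143, a melanosomal receptor, by 0.46 (adjusted p = 0.0438). The melanin list mean was 0.09 higher (camera adjusted p = 0.0331, adjusted p = 0.568 with an estimated correlation). That call was lost without Mfrp rd6 replicate 1 (melanin synthesis and melanosomes 0.05, adjusted p = 0.239), wild-type replicate 2 (0.06, adjusted p = 0.0927) or wild-type replicate 4 (0.07, adjusted p = 0.0853) and with the skeletal muscle mean (0.01, adjusted p = 0.707) or microglia and macrophage mean (0.30, adjusted p = 0.201) as a covariate, and Gpr143 passed only without wild-type replicate 3 among the fits that left out 1 array, with 0.42 to 0.54 and adjusted p up to 0.148 (11 of 20 over all alternatives). Of 20 RPE channels and transporters 0 rose and 2 fell, also adjusted over the list alone, the lactate carrier Slc16a1 by 0.54 (adjusted p = 0.0266) and the organic anion carrier Slco1a4, which fell by 0.48 (adjusted p = 0.0434). The list was not called (adjusted p = 0.654). Slc16a1 passed in 3 of the 7 fits that left out 1 array, those without wild-type replicate 4 or Mfrp rd6 replicates 2 or 3, and Slco1a4 in 0 of 7 (-0.54 to -0.36, adjusted p of 0.065 to 0.106), and over all alternatives they passed in 11 and 6 of 20. Of 18 RPE transcription factors and epithelial markers 0 changed (1 rose and 3 fell adjusted over the list alone), and the list was not called (adjusted p = 0.109), but with the skeletal muscle mean as a covariate the RPE transcription factors and epithelial markers were called lower (-0.16, adjusted p = 0.0205). Its brightest member, the RPE transcription factor Otx2, read 12.17 ± 0.06 and 12.08 ± 0.11. Surface epithelium transcripts were also bright on these arrays (Krt5 at 13.14 in wild type, against 12.87 for Rpe65). The cells that the epithelial markers of this list came from were not tested. Of 18 genes of outer segment phagocytosis 1 rose and 0 fell, also adjusted over the list alone, and the list was not called (adjusted p = 0.419). The riser was Map1lc3a, an LC3 protein of autophagosomes (0.52, adjusted p = 0.0186), which did not pass without wild-type replicate 1 (0.49, adjusted p = 0.0547) or without Mfrp rd6 replicate 1, 2 or 3 (adjusted p of 0.0599 to 0.0692) and passed in 13 of 20 alternatives.

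The mean of rod photoreceptor transcripts in the RPE samples was lower in Mfrp rd6, with overlapping arrays and no single member past the threshold. All 18 measured rod markers had a negative change, 0 fell over all genes and 2 fell adjusted over the list alone. The list mean was 7.87 ± 0.44 (SD, n = 4) in wild type and 7.42 ± 0.15 (SD, n = 3) in Mfrp rd6, a difference of -0.45 (camera adjusted p = 1.9e-05, adjusted p = 0.568 with an estimated correlation). The exact permutation test of the rod means gave p = 0.143. The brightest member, the transducin subunit Gnb1, read 12.78 ± 0.07 and 12.58 ± 0.02 (adjusted p = 0.18, or 0.0271 for Gnb1 with a variance trend and robust moderation). The other rod markers read 5.3 (Nrl) to 10.88 (Reep6) in wild type, so Gnb1 does not stand for the list. Relative to the wild-type rod mean, wild-type replicate 4 stood at -0.44, lower than Mfrp rd6 replicates 2 (-0.39) and 3 (-0.34). Wild-type replicate 3 stood 0.61 above the wild-type rod mean, and without it the difference for the rod photoreceptor markers was -0.25 (adjusted p = 0.000243). With the skeletal muscle mean as a covariate it was -1.02 and with the microglia and macrophage mean, which nearly coincides with genotype, -0.90 (adjusted p = 0.0331).

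Cone photoreceptor genes went apart. Gnb3, the cone transducin beta subunit, rose from 7.29 ± 0.32 (SD, n = 4) to 9.90 ± 0.11 (SD, n = 3), a change of 2.61 (SE 0.16, adjusted p = 3.03e-05). Cngb3, a subunit of the cone cyclic nucleotide-gated channel, rose from 5.76 ± 0.17 to 7.19 ± 0.16 (1.44, adjusted p = 0.000145). Pde6c, the cone phosphodiesterase, fell by 0.88 (adjusted p = 0.0187) and was named after its value was seen. Of 12 measured markers 2 rose and 1 fell (4 and 1 adjusted over the list alone), with Opn1mw at -0.20, Opn1sw at -0.16 and Arr3 at -0.09 among those that did not pass. The list mean was 0.28 and the median -0.05, of opposite sign, and the list was not called (camera adjusted p = 0.0517). It was called higher when wild-type replicate 2 (cone photoreceptor markers 0.29, adjusted p = 0.0357), wild-type replicate 3 (0.35, adjusted p = 0.0215) or Mfrp rd6 replicate 1 (0.32, adjusted p = 0.0404) was left out, and in all in 8 of 19 alternatives. The other 5 were the rod mean as a covariate (0.46, adjusted p = 0.000759), array weights (0.35, adjusted p = 0.0102), wild-type replicate 3 and Mfrp rd6 replicate 2 left out together (0.36, adjusted p = 0.0244), genes with a mean of at least 6 (0.43, adjusted p = 0.0382) and a common median (0.27, adjusted p = 0.044).

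**Figure D2:**
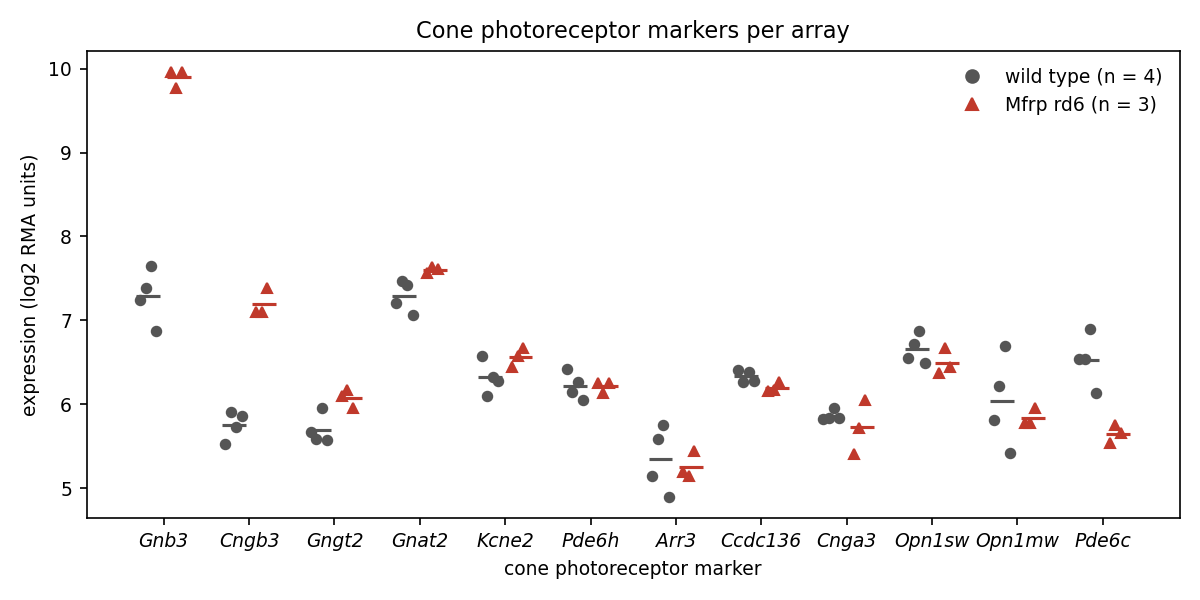
Expression (log2 RMA units, vertical axis) of the 12 cone photoreceptor markers on each array, with circles for the 4 wild-type arrays, triangles for the 3 Mfrp rd6 arrays and horizontal lines for the group means. Gnb3 and Cngb3 are higher on every Mfrp rd6 array than on every wild-type array and Pde6c is lower, while the opsins Opn1mw and Opn1sw differ by -0.20 and -0.16 and did not pass the test.

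The inner retinal neuron and glial lists did not pass. Of 20 inner retinal neuron markers 0 changed (2 rose and 1 fell adjusted over the list alone), with a mean difference of -0.12 (camera adjusted p = 0.482). The brightest member, the glycine transporter Slc6a9, read 12.39 ± 0.05 and 12.41 ± 0.05. The other members read 4.70 (Slc17a6) to 9.67 (Rbpms) in wild type, so Slc6a9 does not stand for the list, and the cells behind its signal were not tested. Of 14 Müller glia and astrocyte markers 0 changed, also adjusted over the list alone, with a mean difference of 0.00 (adjusted p = 0.294), though among genes above the median level the Müller glia and astrocyte markers were called higher (0.09, adjusted p = 0.034), and Apoe read 13.05 ± 0.06 and 13.22 ± 0.04.

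The mean of genes that make and carry polyunsaturated fatty acids, which the outer segments need in quantity, was lower in Mfrp rd6. Of 13 measured members 0 rose and 2 fell (0 and 4 adjusted over the list alone). Mfsd2a, which imports lysophosphatidylcholine carrying docosahexaenoic acid, fell 2.22-fold from 9.82 ± 0.20 (SD, n = 4) to 8.67 ± 0.16 (SD, n = 3), a change of -1.15 (SE 0.12, adjusted p = 0.00114). Elovl2, an elongase of very long polyunsaturated chains, fell from 8.56 ± 0.20 to 7.82 ± 0.21 (-0.74, adjusted p = 0.018). The list mean differed by -0.27 (camera adjusted p = 0.000344, adjusted p = 0.568 with an estimated correlation). The microglia and macrophage mean was higher on the same arrays by 1.81 and the skeletal muscle mean by 1.37, and the difference for polyunsaturated fatty acid synthesis and uptake was -0.82 with the first as a covariate and -0.50 with the second. Elovl2 did not pass without Mfrp rd6 replicate 1 (-0.73, adjusted p = 0.0699) or 3 (-0.64, adjusted p = 0.0621) and passed in 16 of 20 alternatives.

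Cholesterol synthesis and uptake genes were lower as a group. All 16 measured members had a negative change, with 0 falling over all genes and 11 falling adjusted over the list alone. The mean was 10.03 ± 0.09 (SD, n = 4) in wild type and 9.69 ± 0.27 (SD, n = 3) in Mfrp rd6 (difference -0.33, camera adjusted p = 7.16e-07, adjusted p = 0.568 with an estimated correlation). Fdft1, the squalene synthase and brightest member, read 11.21 ± 0.09 and 11.06 ± 0.16. Mfrp rd6 replicate 2 lay lowest, and without it the difference for cholesterol synthesis and uptake was -0.18 (adjusted p = 0.000199). With the skeletal muscle mean as a covariate it was -0.13 (adjusted p = 0.42), and with the microglia and macrophage mean it turned to 1.21 and was called higher (adjusted p = 2.91e-14).

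The other metabolic lists were not called. Of 15 genes of fatty acid oxidation and ketogenesis 0 changed, also adjusted over the list alone (mean difference -0.05, camera adjusted p = 0.305), though fatty acid oxidation and ketogenesis was called lower with the microglia and macrophage mean as a covariate (-0.48, adjusted p = 0.0331), and Acaa2, a thiolase of this pathway, read 11.20 ± 0.07 and 11.23 ± 0.02. Of 14 glycolysis genes 0 changed (2 rose and 0 fell adjusted over the list alone, camera adjusted p = 0.383), with Aldoa at 12.40 ± 0.06 and 12.36 ± 0.05. Of 26 respiratory chain genes 0 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.218). That gene was Ndufa4, a small subunit of the chain, which went from 10.49 ± 0.10 to 9.75 ± 0.07 (-0.75, adjusted p = 0.00112). Ndufa4 passed in 18 of 20 alternatives and not with the skeletal muscle mean (-0.87, adjusted p = 0.0703) or the microglia and macrophage mean (-0.76, adjusted p = 0.999) as a covariate.

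Skeletal muscle transcripts were present in both groups and higher in Mfrp rd6. All 12 markers had a positive change, with 2 rising over all genes and 12 rising adjusted over the list alone. Pvalb, the calcium buffer of fast fibres, rose by 2.18 (SE 0.42, adjusted p = 0.0316), and Myh4, a fast myosin heavy chain, rose from 7.63 ± 0.66 to 9.47 ± 0.52 (1.84, adjusted p = 0.0258). The list mean was 7.23 ± 0.56 (SD, n = 4) and 8.60 ± 0.47 (SD, n = 3), a difference of 1.37 (camera adjusted p = 4.95e-14, adjusted p = 0.551 with an estimated correlation). Relative to the wild-type mean, wild-type replicate 3 stood at 0.82 and the Mfrp rd6 arrays at 1.48, 1.77 and 0.85. In the fits that left out 1 array, Pvalb and Myh4 passed only without wild-type replicate 3 or Mfrp rd6 replicate 3, with adjusted p up to 0.114 and 0.0984, and over all alternatives each passed in 11 of 20. With the microglia and macrophage mean as a covariate the skeletal muscle markers turned to -1.50 and were called lower (adjusted p = 0.0039).

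Of the other tissues of the eye wall, markers of choroidal endothelium were higher in Mfrp rd6. All 16 had a positive change, with 2 rising and 0 falling over all genes (10 and 0 adjusted over the list alone). Plvap, a protein of endothelial fenestrae, rose by 0.57 (adjusted p = 0.0459), and Tek, the angiopoietin receptor, by 0.55 (adjusted p = 0.0389). The list mean differed by 0.40 (camera adjusted p = 7.27e-11, adjusted p = 0.551 with an estimated correlation). The exact permutation test of the list means gave p = 0.0857, and fry gave an adjusted p of 0.126. The skeletal muscle mean was higher on the same arrays by 1.37, and with it as a covariate the choroidal endothelial markers differed by 0.29 (adjusted p = 6.05e-05). When 1 array was left out, Plvap and Tek passed only without wild-type replicate 4, with adjusted p up to 0.144 and 0.118, and over all alternatives they passed in 9 of 20 and 8 of 19.

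The mean of fibroblast, pericyte and scleral markers was slightly lower, with 0 of 16 rising and 1 falling (0 and 3 adjusted over the list alone). Dcn, a proteoglycan of fibroblasts, fell from 10.13 ± 0.26 to 9.20 ± 0.23 (-0.92, adjusted p = 0.014). The list mean differed by -0.16 (camera adjusted p = 0.0355, adjusted p = 0.568 with an estimated correlation). The call on fibroblast, pericyte and scleral markers held in 11 of 20 alternatives. It was lost when only genes above the median level (adjusted p = 0.288) or with a mean of at least 6 (adjusted p = 0.132) were tested, and without wild-type replicate 3 and Mfrp rd6 replicate 2 together (-0.12, adjusted p = 0.147). With the skeletal muscle mean as a covariate the difference was -0.12 (adjusted p = 0.422) and with the microglia and macrophage mean 0.17 (adjusted p = 0.368). The call on these fibroblast, pericyte and scleral markers was also lost without wild-type replicate 1 (-0.16, adjusted p = 0.071), wild-type replicate 4 (-0.14, adjusted p = 0.0853) or Mfrp rd6 replicate 2 (-0.13, adjusted p = 0.133), and Dcn did not pass without Mfrp rd6 replicate 1 (-0.93, adjusted p = 0.0532) or 2 (-0.81, adjusted p = 0.055) and passed in 14 of 20 alternatives. Of 10 markers of choroidal melanocytes and Schwann cells 1 rose and 0 fell (1 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.375). The riser was the cadherin Cdh19 (0.69, adjusted p = 0.0253), which passed in 2 of the 7 fits that left out 1 array, those without wild-type replicate 3 or Mfrp rd6 replicate 3, and in 11 of 19 alternatives.

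The mean of the lens markers was raised on a single array. Of 14 lens markers 0 changed, also adjusted over the list alone, and the list mean stood at 1.15 above the wild-type mean on Mfrp rd6 replicate 2 against -0.11 and 0.09 on the other Mfrp rd6 arrays. The brightest member, the crystallin Cryab, read 10.82 ± 0.09 and 10.96 ± 0.02. Camera called the list higher (mean difference 0.38, adjusted p = 0.0212, adjusted p = 0.568 with an estimated correlation), and without Mfrp rd6 replicate 2 the lens markers differed by -0.01 (adjusted p = 0.821). The call was also lost without wild-type replicate 2 (0.34, adjusted p = 0.0528) or 4 (0.34, adjusted p = 0.0591), and without Mfrp rd6 replicate 1 the difference was 0.62 (adjusted p = 0.000167). The call on the lens markers was lost as well with cyclic loess (adjusted p = 0.0525), with genes of a mean of at least 6 (adjusted p = 0.0957), without wild-type replicate 3 and Mfrp rd6 replicate 2 together (0.03, adjusted p = 0.63) and with the skeletal muscle mean as a covariate (-0.12, adjusted p = 0.954), and with the microglia and macrophage mean the difference turned to -3.29 and the list was called lower (adjusted p = 6.25e-12). Red cell markers had 3 measured members, too few for the set test, with 0 changed, also adjusted over the list alone. Globins of the list lay only on shared probe sets, which were not used. Alas2, which starts haem synthesis in red cell precursors, read 7.07 ± 0.05 and 7.02 ± 0.24. The 4 measured X-inactivation and Y-linked genes did not change either, also adjusted over the list alone. Eif2s3y, on the Y chromosome, read 8.87 ± 0.15 in wild type and 8.79 ± 0.24 in Mfrp rd6, and Xist, chosen after its values were seen, lay between 4.27 and 4.48 on all arrays.

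**Figure D3:**
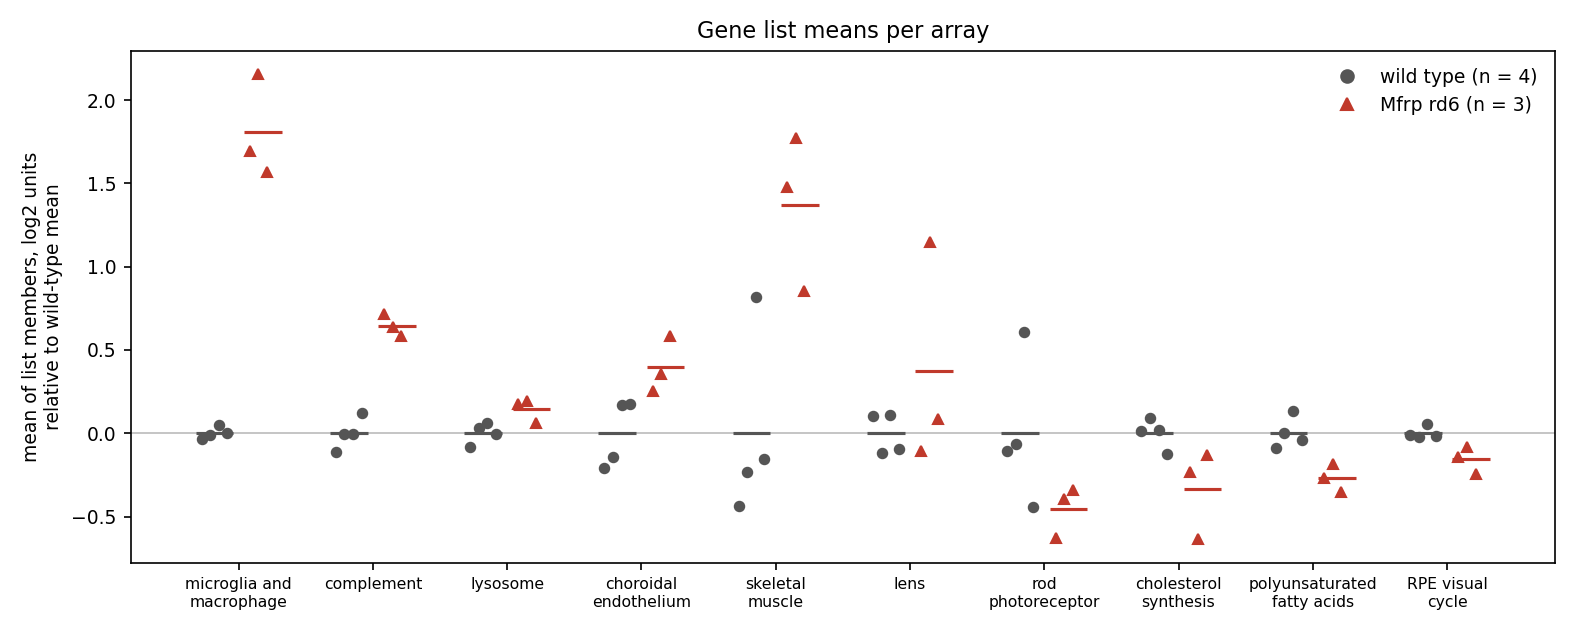
Mean of the members of 10 gene lists on each array, in log2 units relative to the wild-type mean (vertical axis), with circles for the 4 wild-type arrays, triangles for the 3 Mfrp rd6 arrays and horizontal lines for the group means. The microglia and macrophage mean lies at 1.57 to 2.16 on the Mfrp rd6 arrays, the skeletal muscle mean at 0.85 to 1.77, and the lens mean is raised on 1 Mfrp rd6 array only.

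Among stress and immediate early genes a single gene rose. Of 16 immediate early genes 1 rose and 0 fell, also adjusted over the list alone: Nr4a1, a nuclear receptor induced within minutes of stimulation, by 0.59 (adjusted p = 0.038). The list mean was 0.27 higher (camera adjusted p = 0.000864, adjusted p = 0.568 with an estimated correlation). Without Mfrp rd6 replicate 1 the immediate early genes differed by 0.14 (adjusted p = 0.113) and with the skeletal muscle mean as a covariate by 0.10 (adjusted p = 0.187), and Nr4a1 passed only without Mfrp rd6 replicate 3 among the fits that left out 1 array, with adjusted p up to 0.0992 (8 of 19 over all alternatives). Of 17 NRF2 and oxidative stress genes 0 changed (3 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.691), with the metallothionein Mt2 at 12.70 ± 0.05 and 12.91 ± 0.05 (adjusted p = 0.0175 for Mt2 with a variance trend and robust moderation, 0.152 without). Of 16 genes of the unfolded protein and integrated stress response 0 changed, also adjusted over the list alone, and the list was not called (mean difference -0.07, adjusted p = 0.0517). The chaperone Calr read 12.00 ± 0.05 and 11.89 ± 0.08. Without wild-type replicate 4 (unfolded protein and integrated stress response -0.09, adjusted p = 0.0284) or Mfrp rd6 replicate 2 (-0.10, adjusted p = 0.00702) the list was called lower, and in all in 6 of 20 alternatives. These included the microglia and macrophage mean (-0.49, adjusted p = 0.00304) or skeletal muscle mean (-0.23, adjusted p = 0.0122) as a covariate and wild-type replicate 3 and Mfrp rd6 replicate 2 left out together (adjusted p = 0.018). Without Mfrp rd6 replicate 3 the unfolded protein and integrated stress response differed by -0.02 (camera adjusted p = 0.398).

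Matrix and signalling genes showed 2 single changes and no group shift. In the list for Bruch membrane and extracellular matrix, 1 of 21 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.662). Col8a1, a short-chain collagen, rose by 0.47 (adjusted p = 0.0419), and the secreted serine protease Htra1 fell by 0.53 (adjusted p = 0.0267). When 1 array was left out, Col8a1 passed only without wild-type replicate 3, and Htra1 only without wild-type replicate 3 or Mfrp rd6 replicate 3, and over all alternatives each passed in 10 of 20. Of 15 mesenchymal transition genes 0 changed, also adjusted over the list alone (camera adjusted p = 0.482), and the intermediate filament Vim read 10.92 ± 0.15 and 10.84 ± 0.10. Of 23 genes of Wnt and frizzled signalling 0 changed, also adjusted over the list alone (camera adjusted p = 0.481), with the secreted inhibitor Sfrp1 at 11.98 ± 0.06 and 12.09 ± 0.04.

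Circadian clock genes had a slightly higher mean in Mfrp rd6, called as a set only by camera with the preset correlation (fry adjusted p = 0.209). Of 14 members 0 changed, also adjusted over the list alone, and the list mean was 0.09 higher in Mfrp rd6 (camera adjusted p = 0.0212, adjusted p = 0.568 with an estimated correlation). The brightest member, the clock repressor Nr1d1, read 11.68 ± 0.08 and 11.68 ± 0.06. The call on the circadian clock list was lost without wild-type replicate 1 (0.06, adjusted p = 0.0674) or Mfrp rd6 replicate 1 (0.08, adjusted p = 0.116), with array weights (adjusted p = 0.0678), and with the rod mean (adjusted p = 0.158), skeletal muscle mean (adjusted p = 0.151) or microglia and macrophage mean (adjusted p = 0.121) as a covariate. The exact permutation tests of the list means gave adjusted p of at least 0.162 for all 34 lists. Of the 32 lists that the set test could take, camera with the preset correlation called 10 higher and 5 lower, camera with an estimated correlation called 0, with 2 at an unadjusted p under 0.05, and fry called 2. With the skeletal muscle mean as a covariate, which was added after seeing the data, 5 lists were called higher and 5 lower. With the microglia and macrophage mean as a covariate the differences for the lysosome, skeletal muscle, lens, fibroblast and cholesterol lists changed sign.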

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

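The tests of cell sources for the microglial, muscle and cone patterns were chosen after those results were seen, and the counts over other splits of the arrays were planned.

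The count of changed genes exceeded what regrouping the arrays gave. Of the 35 splits of the 7 arrays into 3 and 4, 1, the real one, gave as many as 429 genes, and the highest other split gave 3. Over 35 splits a permutation p cannot go below 0.0286, so chance is unlikely for this count but not excluded. Regrouping also cannot tell genotype from the age difference in the age field. For the gene lists chance is not excluded either: 2 of the 35 splits called as many as the 15 lists of the real split. The highest other split, with wild-type replicates 1, 2 and 3 against the remaining arrays, called 16. That split is the real one with wild-type replicate 4 moved, so it still holds much of the genotype contrast. A split that mixed the genotypes, with wild-type replicates 2 and 3 and Mfrp rd6 replicate 2 on one side, called 10. Another, the real one with wild-type replicate 4 and Mfrp rd6 replicate 2 exchanged, called 14. List calls with the preset correlation therefore carry less weight here than the calls on single genes.

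Markers of microglia and macrophages were higher in Mfrp rd6 by a mean of 1.81, with 17 of 21 past the threshold, while Csf1r and Itgam, already at 10.09 and 10.47 in wild type, did not pass. Carry-over with neural retina stays open: the median change of 38 rod and inner retinal neuron markers was -0.212 (95% bootstrap interval over genes -0.483 to -0.109), but their mean did not separate the groups (exact permutation p = 0.0857), and a degenerating retina can lose rod RNA and hold more immune cells. Carry-over with blood stays open too, since only 3 red cell markers had a probe set of their own, too few to decide. Their mean difference was 0.016 (95% interval -0.223 to 0.255). The globins of the list lay only on shared probe sets, which were not used. More microglia or macrophages in the pellet remain a candidate. The called markers deviated together over the 3 Mfrp rd6 arrays with a mean correlation of 0.925, where random sets of risers outside the list had a median of 0.146 (-0.031 to 0.477 over 95% of sets). Joint activation of the cells would also make the markers deviate together, so the correlation does not tell it from a larger number of cells. Activation of an unchanged number of cells, the genotype itself and the 12-week age that the age field gives to the mutant samples stay open, as untested.

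Skeletal muscle markers were higher in Mfrp rd6 by a mean of 1.37, with Pvalb and Myh4 past the threshold. Carry-over of extraocular muscle with the eyecup is a candidate explanation: the 12 markers deviated together over the 4 wild-type arrays, where no mutation acts, with a mean correlation of 0.885 against a median of 0.017 for random sets of like level (-0.079 to 0.25 over 95% of sets). Ckm, Tnnt3 and Acta1, the brightest of them in wild type, read 8.23, 8.18 and 8.17 there and 9.94, 9.92 and 9.70 in Mfrp rd6, and no sort that would remove muscle is named in the labels. A difference in how the mutant eyes were dissected and an effect of genotype or age on the amount that comes loose stay open, as untested.

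Gnb3 and Cngb3 were higher in Mfrp rd6 by 2.61 and 1.44. More cone photoreceptor RNA in the pellet is argued against as the source, since the median change of the other 10 cone markers was -0.11 (95% bootstrap interval -0.168 to 0.241), below the change of either gene, and the highest of them, Gngt2, differed by 0.38. This has limits. The bootstrap treats genes as independent, and the 10 markers read only 5.3 (Arr3) to 7.29 (Gnat2) in wild type, where changes can be understated. Cngb3, which rose, read 5.76 there. A changed make-up of cone transcripts, transcription of these 2 genes in another cell type, and an effect of genotype or age, stay open, as untested.

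Among 97 results examined for an array far from the rest of the 4 wild-type arrays, 5 had one, and chance gives about 1 in 20. B2m read 12.33 on wild-type replicate 2 and 12.23 to 12.24 on the others. Mt2 read 12.62 on wild-type replicate 1 and 12.72 to 12.73 on the others. The mean of the RPE visual cycle list was 11.773 on wild-type replicate 3 and 11.696 to 11.709 on the others. The mean of the Müller glia and astrocyte list was 8.894 on wild-type replicate 4 and 8.674 to 8.694 on the others. The mean of the circadian clock list was 9.281 on wild-type replicate 1 and 9.402 to 9.417 on the others. The Mfrp rd6 arrays, 3 in number, were too few for this check.

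Probe sets outside the gene comparison also differed between the groups. With all 35556 probe sets in the fit, limma called 20 that carry no gene symbol (13 higher, 7 lower) and 6 that carry several (3 higher, 3 lower).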

How the results depend on the processing

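Leaving out wild-type replicate 3 with Mfrp rd6 replicate 2 and the skeletal muscle covariate were tests chosen after seeing the data, and the others were planned. Against 429 changed genes (267 higher, 162 lower) and lists called 10 higher and 5 lower, quantile normalization gave 500 genes, a common median 430, cyclic loess 494 and the mean of a gene's probe sets 433, with limma throughout. Each kept the direction of all 429. The higher share was 62.2% and stayed within 59.1% to 69.2% under these scalings. Genes above the median level gave 302 lower calls (higher share 41.5%) and 3 lists lower, and genes with a mean of at least 6 also gave 3 lists lower, and the RPE visual cycle (adjusted p = 0.119 and 0.0667) and the fibroblast list (0.288 and 0.132) were the lower lists lost under both filters, which test fewer genes. A variance trend with robust moderation gave 718 changed genes, 355 of them lower (higher share 50.6%), and array weights gave 679, with 405 higher and 274 lower, and the cause was not tested. A minimum change of 1 log2 unit left 104, with 88 higher and 16 lower. Testing all 35556 probe sets gave 167, with 117 higher and 50 lower, and 134 of the 429 remained, with a prior of 2.71 degrees of freedom against 4.56. With an estimated correlation camera called 0 lists higher and 0 lower.

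With the replicate number as a block, 225 genes changed, 166 higher and 59 lower, and 205 of the 429 remained. Wild-type replicate 4 has no Mfrp rd6 array of its number and adds nothing to this contrast, so the rod difference (-0.601) equals that without wild-type replicate 4. Of the 41 named genes past the threshold 27 remained, and Rdh10 (-0.573, adjusted p = 0.0558) was among those lost. The call on fibroblast, pericyte and scleral markers was lost (-0.136, adjusted p = 0.0709), while the lists for the interferon response (0.168, adjusted p = 0.000936) and the unfolded protein and integrated stress response (-0.091, adjusted p = 0.0298) were called. The values gave no sign that the numbers pair the samples: deviations of same-numbered arrays correlated at -0.303, -0.073 and 0.036, and not every array correlated best with its own number. So few pairs cannot exclude a shared litter, day or batch, and the labels do not say what the numbers mark. With the rod marker mean as a covariate 164 genes changed, 135 higher and 29 lower, with 151 of the 429 remaining. With the skeletal muscle mean 49 changed, 22 higher and 27 lower, with 43 remaining, 5 lists were called higher, and the lens list turned to -0.116. Without wild-type replicate 3 and Mfrp rd6 replicate 2 together, 193 changed, 155 higher and 38 lower, with 168 remaining. Fewer residual degrees of freedom are part of these fits' construction, and the cause was otherwise not tested.

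With the microglia and macrophage mean as a covariate limma called 0 genes, 0 higher and 0 lower (929 at an unadjusted p under 0.05), and 4 lists higher. That mean nearly coincides with genotype (7.12 ± 0.04 against 8.93 ± 0.31), so the fit leaves little of the contrast to estimate. Of the 429 genes, 286 kept their sign. Among the lists and named genes past the threshold, those that turned were lysosome -0.206, fibroblast, pericyte and scleral markers 0.167, skeletal muscle -1.501, lens -3.289, cholesterol synthesis 1.209, Trem2 -0.33, Ctsz -0.27, Dcn 0.228, Cdh19 -0.048, Pvalb -1.959, Myh4 -1.368 and Htra1 0.479. Under no other setting run did a called gene reverse.

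Leaving out each array in turn gave 211 (without Mfrp rd6 replicate 1) to 325 changed genes, 152 to 235 higher and 59 to 108 lower, with 8 to 11 lists higher and 4 to 5 lower. Camera's call with the preset correlation held in 7 of 7 such fits for the rod list (mean difference -0.601 to -0.252), which was not called with an estimated correlation (adjusted p = 0.568) and had an exact permutation p of 0.143. It also held in 7 of 7 for the microglia and macrophage list (1.632 to 1.925, adjusted p = 0.217 with an estimated correlation), and the Mfrp probe set passed in 0 of 7 (-0.197 to -0.107). Of the 41 named genes past the threshold, 23 remained without Mfrp rd6 replicate 1 and 35 without wild-type replicate 3. A list's own mean as a covariate gives that list no value. Other background corrections and a slide or scan block were not run, as no scanner values or slides were used here. Signal over background limits dim genes: 58 of the 429 had a mean level under 6.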

Other observations

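All tests in this part were chosen after the data had been seen.

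Nicotinic acetylcholine receptor subunits went apart in the Mfrp rd6 samples, and the cells that their transcripts came from were not tested. Of 16 measured, 3 rose and 1 fell (limma, adjusted over all genes). Chrnb4 rose from 9.52 ± 0.16 (SD, n = 4) to 10.97 ± 0.13 (SD, n = 3), a change of 1.46 (SE 0.10, adjusted p = 8.42e-05), and Chrna3 rose from 6.90 ± 0.42 to 8.35 ± 0.17 (1.45, adjusted p = 0.0058). Chrna4 rose by 0.91 (adjusted p = 0.0449), and Chrna7 fell by 0.44 (adjusted p = 0.033). Chrna5, which lies next to Chrna3 and Chrnb4 on chromosome 9 in the GRCm38.p6 gene table, read 4.44 ± 0.26 and 4.43 ± 0.19. Among genes outside the immune lists, the sulfatase Sulf2 rose by 2.39 (adjusted p = 4.36e-06), the synaptic adhesion protein Nlgn3 by 1.48 (adjusted p = 5.11e-05), the protease inhibitor A2m by 1.34 from 11.33 ± 0.16 to 12.67 ± 0.08, and Aanat, the enzyme that acetylates serotonin in melatonin synthesis, by 0.95 (adjusted p = 0.0027).

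Genes that fell, beside those named by the rule, included these. Slco1c1, a thyroid hormone carrier, fell from 10.69 ± 0.12 to 9.56 ± 0.34 (-1.13, adjusted p = 0.0039), and the guidance cue Sema3c from 11.36 ± 0.05 to 10.65 ± 0.12 (-0.71, adjusted p = 0.00139). Aldh1a2, which makes retinoic acid, fell by 0.76 (adjusted p = 0.00497), Vipr2, a receptor for vasoactive intestinal peptide, fell by 1.01 (adjusted p = 0.00553), and the endothelin Edn3 fell by 0.70 (adjusted p = 0.014).

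Transcripts of surface epithelium were present on all arrays, although the labels' protocols state that the cornea was taken off. Krt5 read 13.14 ± 0.03 (SD, n = 4) in wild type and 13.15 ± 0.01 (SD, n = 3) in Mfrp rd6, and Krt13 read 12.56 ± 0.07 and 12.44 ± 0.11. Of 23 measured genes in a list of 24 genes of corneal and conjunctival epithelium, written after the calls but before these values were seen, 20 had a negative change and 0 passed over all genes (median -0.14, camera p = 2.61e-05, p = 0.0618 with an estimated correlation).

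Of muscle genes outside the fixed list, 4 are given, picked because they had passed the test. Atp2a1, the calcium pump of fast fibres, rose by 2.21 (adjusted p = 0.0422), the calcium-binding protein Casq1 by 1.61 (adjusted p = 0.033), Myot by 1.42 (adjusted p = 0.0421) and the giant protein Ttn by 1.40 (adjusted p = 0.0417). Of the lens crystallins, Cryaa read 9.75 on Mfrp rd6 replicate 2 and 5.69 to 6.15 on the other arrays, Cryba1 8.27 and 4.17 to 4.43, and Crygs 8.11 and 4.59 to 5.04.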
